A study of Mus musculus with 4 samples.

How the data were processed

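The series comprises 4 ChIP-seq samples of cervical spinal cord from wild-type mouse embryos at stage e12.5, namely a Hoxa5 and a Pbx1 immunoprecipitation and an input for each. Each pool held tissue of multiple embryos, and libraries were made by Active Motif and sequenced as 75-nucleotide reads on a NextSeq 500, per the labels' protocols. The input samples are titled as inputs while their antibody label reads IgG, so which of these they were is not settled by the labels. They were not analysed here. Alignment and calling tools named in the submitters' processing notes are Bowtie2 (version 2.3.5.1), SAMtools (version 1.10) and MACS2, with the mouse build mm10. The MACS2 version and options, the control used and the filter applied to the peaks are not given in the sources used here.

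The authors deposited 1 peak list per ChIP sample in narrowPeak layout. The deposited fold enrichment of each peak is the ratio of signal at the summit to the local background as the authors' peak caller gave it. The deposited −log10 p-value and −log10 q-value are the peak caller's own significance of each peak. The deposited score equals 10 times the −log10 q-value cut to a whole number in every row. The deposited lists also give the distance of the summit from the peak start in bp. Peaks in the lists carry numbers up to 15331 (Hoxa5) and 41924 (Pbx1), so 29.4% and 35.5% of these numbers were kept by the authors. No kept peak had a fold enrichment below 5.00 (Hoxa5) or 6.00 (Pbx1), or a −log10 q-value below 7.00 or 8.75. Because the lists passed different floors and come from libraries of unknown depth, their lengths and their fold enrichments were not compared with each other.

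Coordinates are those of the lists, counted from 1. Genes were taken from a RefSeq gene table of GRCm38.p6, the assembly behind mm10, which gives the start, end and type of each gene but no strand, exons or sequence. Transcription start sites could therefore not be located, and the distance to the nearest gene end was used in their place. Gene ends are those of protein-coding genes unless all annotated genes are named. Exons and introns were not separated. Motif content, planned with 5 alternatives, was not run because no genome sequence was used here. Peaks on chromosomes 1 to 19 and X were analysed. The 2 Hoxa5 and 11 Pbx1 peaks elsewhere were left out.

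A Hoxa5 peak was called shared when it overlapped a Pbx1 peak by at least 1 bp (bedtools 2.31.1). Overlap was set against 1000 random placements of the Hoxa5 peaks, each keeping its width and chromosome, between the first and last gene or peak of the chromosome. Assembly gaps were not excluded. Peak strength was compared by a two-sided permutation test of the difference of medians with 100000 permutations. Shares have 95% Wilson intervals and were compared by Fisher's exact test, two-sided, adjusted by the Benjamini-Hochberg method over 3 comparisons. Expected shares near gene ends and the densest windows used 200 placements. Each summit was assigned to the nearest protein-coding gene within 100 kb, at distance 0 inside a gene, and in overlapping genes to the gene with the nearest end; 97.8% of Hoxa5 and 81.8% of Pbx1 peaks were assigned. Each of 20 gene lists was compared with 10000 random lists of the same size, which permutes list membership among genes, matched in 20 bins on the length of the territory from which a gene draws peaks (500 bp grid). Two-sided p-values were adjusted over 60 tests, with a threshold of 0.05, and 0.0002 was the smallest unadjusted p these lists could give. The 20 lists held 445 distinct genes, of which 444 matched by symbol and 1 by an older symbol (Drgx, listed as Prrxl1). The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

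The lists, the tests, the settings and the rule for the genes named in the text were chosen before the data were examined. Gene assignment departs from that plan. It had been set to the nearest transcription start site, and gene bodies were used in its place. The rule names, for each list and peak class, at most 4 genes with the strongest assigned peak; the 10 genes with the strongest Hoxa5 peak, the 10 with the strongest Pbx1 peak and the 10 with the most shared peaks; and Hoxa5, Hoxc5, Hoxb5, Pbx1, Pou3f1, Alcam, Ptn, Pappa, Cdh10 and Isl1 whatever they showed. Windows dense in peaks are named by the genes they hold. A peak given for a gene is one assigned to it, which can lie up to 100 kb away. Alternatives tried were stricter overlaps, the stronger 50% of each list and a Pbx1 list cut to the 4497 strongest peaks, both ranked by the deposited −log10 q-value, local shifts of 10 to 100 kb, peaks over 1 kb from a gene end, other distances to genes (500 bp, 5 kb and 20 kb, or no limit), all annotated genes, unmatched random lists, and windows of 50 kb. Placement by distance to a random gene end, leaving out the Hox genes, and assignment to the nearest gene end were added later, as were the shorter Pbx1 list for the gene lists, widths compared by summits within 100 bp, the strongest 10% of each list near gene ends, the quartiles of fold enrichment and the coverage of the Hox clusters.

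The procedures were tested on simulated data. Of 500 Hoxa5 peaks planted on Pbx1 peaks among 4497, 498 were recovered above placements, and with none planted the ratio was 1.06. With no signal planted, 4.5% of 200 random gene lists and 5% of 100 median tests were called. With 12 of 25 genes planted all lists were called, as were all median tests with a shift of 10%. A call in these checks was an unadjusted p under 0.05, so power for shorter lists after adjustment was not measured. The ratio with none planted used the same placements as the test, so it checks the code only.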

Results

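Binding sites of the transcription factors Hoxa5 and Pbx1 were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in cervical spinal cord of wild-type mouse embryos at stage e12.5. Hoxa5 is a homeodomain protein of the Hox5 paralog group, which phrenic motor neurons, the neurons that innervate the diaphragm, require for their development. Pbx1 is a homeodomain protein of the TALE class and a DNA-binding cofactor of Hox proteins. The 4 samples were 1 Hoxa5 ChIP, 1 Pbx1 ChIP and 1 input for each antibody, and tissue of several embryos was pooled in each. The inputs were not analysed here. No group had replicates, so no value below has an error across animals. The Hoxa5 list held 4499 peaks with a median fold enrichment of 6.18 and a highest value of 33.2. The Pbx1 list held 14875 peaks with a median of 8.42 and a highest value of 117. Fold enrichments are the authors' own and are compared only within a list. Median peak widths were 400 bp for Hoxa5 and 457 bp for Pbx1, and the peaks covered 2.28 Mb and 8.25 Mb. Sequencing depth is unknown, since the lists give no read totals. Intervals are 95% Wilson intervals, which cover counting error only, and p-values describe these lists, not animals, because neither peaks nor genes are biological replicates.

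The comparison implied by the pair of antibodies was which Hoxa5 sites also carried Pbx1. The genes with the most Hoxa5 peaks overlapped by a Pbx1 peak were Gse1, with 11 of its 25 Hoxa5 peaks, and the Hox genes Hoxb3, with 10 of 12, and Hoxc4, with 10 of 17. All 8 Hoxa5 peaks assigned to Tle3, a Groucho-family co-repressor, met a Pbx1 peak, as did all 6 at the zinc finger gene Sall1 and all 6 at Zmiz1. At Hoxa3, 8 of 15 Hoxa5 peaks were shared, at Zfp503 7 of 9, at Hoxd3 6 of 10 and at Polg 5 of 12. These counts depend on the assignment of peaks to gene bodies. The annotated body of Hoxa3 spans the Hoxa5 gene and that of Hoxb3 spans Hoxb4. Shared peaks assigned to Hoxc4 lay up to 49139 bp from it. Genes with long bodies or wide territories can therefore rank high. Over chromosomes 1 to 19 and X, 1355 of 4497 Hoxa5 peaks overlapped a Pbx1 peak, a share of 30.1% (interval 28.8 to 31.5). In the other direction, 1286 of 14864 Pbx1 peaks overlapped a Hoxa5 peak, or 8.65% (8.21 to 9.11). Random placement of the Hoxa5 peaks on their own chromosomes gave 29.6 ± 5.50 overlapping peaks (SD over 1000 placements) and at most 47. The observed number was 45.8-fold higher (one-sided permutation p over placements = 0.000999, the smallest that 1000 placements can give). The ratio was 16.0 when each peak was moved by 10 to 100 kb, and 9.11 when each peak kept its distance to a gene end but was set at a random gene end, a placement chosen after the data were seen. With overlap defined by summits within 100 bp, 516 Hoxa5 peaks, or 11.5%, were shared, which was 92.4-fold above placements. Hoxa5 peaks were assigned to 3317 of 21631 protein-coding genes and Pbx1 peaks to 6254. Of these, 1883 genes carried both, against 959 for independent lists of those lengths, and 1065 carried a shared peak. The 959 takes all genes as equally likely to hold a peak. Genes with longer territories draw more peaks, so part of the excess can arise without a link between the factors.

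Shared peaks were stronger than unshared peaks in both lists, and shared sites were among the strongest Hoxa5 peaks. Of the 10 strongest Hoxa5 peaks, 7 overlapped a Pbx1 peak, among them those at Tecr (fold enrichment 25.6), Hoxb3 (23.3), Hoxb6 (23.0), Sox11 (22.0) and Hoxb8 (21.5). The median fold enrichment of Hoxa5 peaks was 6.48 (quartiles 5.79 and 7.72) in 1355 shared peaks and 6.16 (5.61 and 6.91) in 3142 unshared peaks. The difference was 0.324 (two-sided permutation test over peaks, p = 1e-05, the smallest that 100000 permutations can give). Shared Pbx1 peaks had a median of 10.4 (7.38 and 18.8) against 8.28 (6.85 and 11.4) in unshared ones, a difference of 2.11 (permutation p = 1e-05). With sharing defined by summits within 100 bp, the differences were 0.294 (permutation p = 6e-05) and 2.93 (permutation p = 1e-05). Shared peaks had median widths of 439 bp against 388 bp for Hoxa5 and 796 bp against 439 bp for Pbx1 (permutation p = 1e-05 for each), but a wide peak meets the overlap of 1 bp more easily. By summits within 100 bp, a test added after the data were seen, the widths were 388 bp against 402 bp for Hoxa5 (permutation p = 0.252) and 698 bp against 452 bp for Pbx1 (permutation p = 1e-05), so only shared Pbx1 peaks were wider by both definitions. In the top quartile of fold enrichment, 42.7% of Hoxa5 peaks (39.8 to 45.6) and 15.2% of Pbx1 peaks (14.1 to 16.4) were shared. In the bottom quartile these shares were 25.2% (22.8 to 27.9) and 6.19% (5.46 to 7.01).

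**Figure D1:**
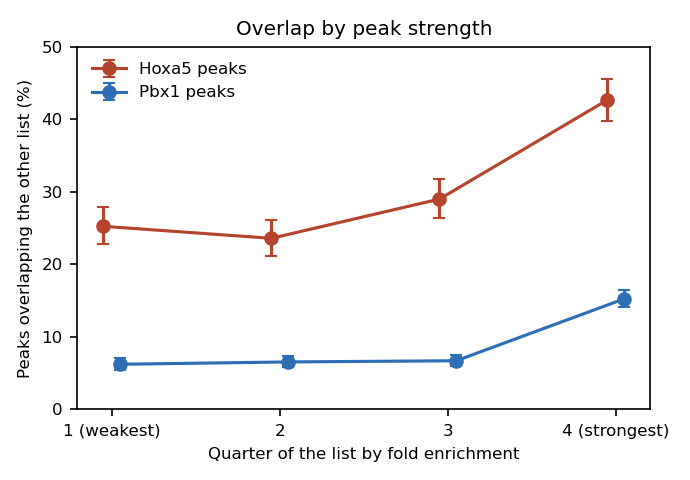
Share of Hoxa5 peaks that overlap a Pbx1 peak and of Pbx1 peaks that overlap a Hoxa5 peak (y axis, %), by quartile of fold enrichment within each list (x axis); bars are 95% Wilson intervals. The Hoxa5 share was 25.2%, 23.6%, 29.0% and 42.7% from the weakest to the strongest quartile, and the Pbx1 share was 6.19%, 6.51%, 6.67% and 15.2%.

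Over the full lists, Hoxa5 peaks lay close to the ends of protein-coding genes more often than Pbx1 peaks did. The shares were also apart in the top quartile of fold enrichment, at 52.1% for Hoxa5 and 26.05% for Pbx1. They lay close together in the strongest 10% of each list. The gene table gives no strand, so a gene end here is either the start or the end of a gene. Of 4497 Hoxa5 summits, 2388 were within 1 kb of a gene end (53.1%, 51.6 to 54.6), 32.3% lay elsewhere inside a gene and 14.6% outside genes. Of 14864 Pbx1 summits, 2886 were near a gene end (19.4%, 18.8 to 20.1), 39.6% were inside and 40.9% outside genes. The odds ratio of Hoxa5 against Pbx1 peaks was 4.70 (Fisher's exact test, two-sided, with a p below what the software can represent). In the strongest 10% of each list, a cut added after the data were seen, the share near a gene end was 41.4% for Hoxa5 (37.0 to 46.0) and 36.6% for Pbx1 (34.2 to 39.1) by fold enrichment (odds ratio 1.23, unadjusted Fisher's exact test, p = 0.0670). Ranked by −log10 q-value, the shares were 38.5% (34.1 to 43.1) and 39.8% (37.3 to 42.3), with an odds ratio of 0.949 (unadjusted Fisher's exact test, p = 0.660). Random placements put 3.25% of Hoxa5 and 3.12% of Pbx1 peaks near a gene end, so the observed shares were 16.4-fold and 6.23-fold higher. Among Pbx1 peaks, 50.9% of shared (48.2 to 53.7) but 16.4% of unshared peaks (15.8 to 17.1) lay near a gene end (odds ratio 5.28, adjusted p = 5.94e-158, Fisher's exact test). A shared Pbx1 peak lies at a Hoxa5 peak by definition. This contrast therefore follows in large part from the difference between the full lists and is no separate result. Among Hoxa5 peaks the shares were 51.7% (49.0 to 54.3) and 53.7% (52.0 to 55.5), and the difference did not pass Fisher's exact test (adjusted p = 0.204).

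**Figure D2:**
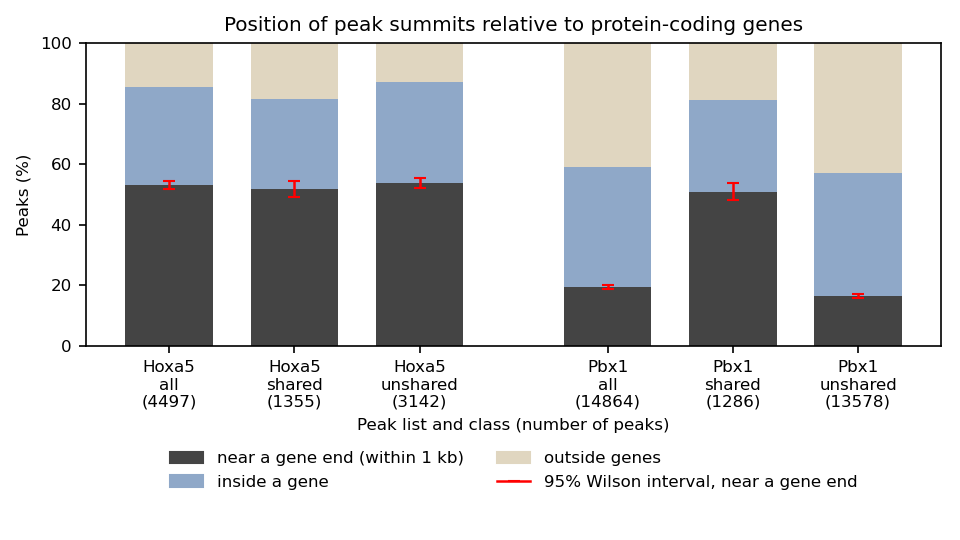
Share of peak summits near a gene end (within 1 kb), elsewhere inside a gene or outside genes (y axis, %), for all, shared and unshared peaks of each list (x axis, with the number of peaks); red bars are 95% Wilson intervals of the share near a gene end. That share was 51.7% in shared and 53.7% in unshared Hoxa5 peaks, and 50.9% in shared and 16.4% in unshared Pbx1 peaks.

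The strongest peaks of the 2 lists lay at different genes. The strongest Hoxa5 peak, with a fold enrichment of 33.2, was inside Rimbp3 (chromosome 16, 17208618 to 17209583, mm10). It was followed by a peak 10366 bp from the co-repressor gene Cbfa2t3 (27.3) and a peak inside Tecr (chromosome 8, 83584693 to 83585455), which encodes a reductase of fatty acid elongation. A peak 237 bp from Setd1a, a histone H3 lysine methyltransferase gene, reached 21.19, and a peak 748 bp from Dand5, a Nodal antagonist gene, reached 21.15. Another, of 21.8 (chromosome 3, 88213014 to 88217337), was 27440 bp from the nearest protein-coding gene, Rhbg, and overlapped the microRNA gene Mir9-1. All 10 strongest Pbx1 peaks were within 505 bp of a gene end, against 4 of the 10 strongest Hoxa5 peaks within 1 kb. The Pbx1 peaks were at Rragc (117, chromosome 4, 123916682 to 123918209), Foxo1 (114, chromosome 3, 52267589 to 52269126), Cdr2 (110), Tom1 (104), Ankhd1 (102), Maco1 (99.6), Rbm27 (97.7), Me2 (97.4), Atp5b (96.9) and Rab11b (95.4). Rragc encodes a Rag GTPase of nutrient sensing, Foxo1 a forkhead factor of insulin signalling and Atp5b a subunit of the mitochondrial ATP synthase. Hoxa5 peaks overlapped 6 of these 10, with fold enrichments of 7.45 at Cdr2, 5.004 at Tom1, 5.20 at Ankhd1, 7.06 at Rbm27, 8.43 at Atp5b and 5.83 at Rab11b.

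Peaks of both factors lay at the Hox genes themselves, which specify position along the body axis. Of 39 Hox genes, 29 had an assigned Hoxa5 peak, 27 a Pbx1 peak and 21 a shared peak. Permuted gene lists of the same size and territory length averaged 4.72, 6.27 and 1.38 genes (adjusted permutation p = 0.000706 for each). That was the lowest value of the 60 list tests, and other lists reached it too. The random lists drew genes independently, whereas Hox genes lie side by side in clusters. These p-values treat neighbouring Hox genes as independent and can overstate the evidence. The Hoxa cluster (chromosome 6, 52155367 to 52260880) held 37 Hoxa5 and 20 Pbx1 peaks, which covered 39.7% and 34.5% of its length. The Hoxb cluster (chromosome 11, 96194316 to 96368254) held 32 and 26 peaks that covered 43.2% and 14.6%. The Hoxc cluster (chromosome 15, 102921131 to 103036856) held 20 and 10 peaks covering 15.1% and 7.38%, and the Hoxd cluster (chromosome 2, 74668225 to 74765142) held 16 and 15 covering 17.1% and 17.6%. The widest Hoxa5 peak of the list, 20024 bp, was assigned to Hoxb5 and had a fold enrichment of 13.7. The strongest Hoxa5 peaks of the group were assigned to Hoxb3 (23.3), Hoxb6 (23.0), Hoxb8 (21.5) and Hoxb2 (20.1), and the strongest Pbx1 peaks to Hoxc4 (63.5, 24794 bp from the gene), Hoxb3 (48.7), Hoxd3 (45.2) and Hoxa3 (45.1). The Hoxa5 gene (chromosome 6, 52201754 to 52204587) carried 2 Hoxa5 peaks, the stronger of 9.15, both overlapped by its 1 Pbx1 peak of 28.0. Its paralog Hoxc5 (chromosome 15, 103014008 to 103017429) had 2 Hoxa5 peaks, the stronger of 12.7, and 1 Pbx1 peak of 18.0, and Hoxb5 (chromosome 11, 96303512 to 96306121) had a Pbx1 peak of 14.8. Of 105 Hoxa5 peaks in the clusters, 55 (52.4%) overlapped a Pbx1 peak, and of 71 Pbx1 peaks, 51 (71.8%) overlapped a Hoxa5 peak.

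**Figure D3:**
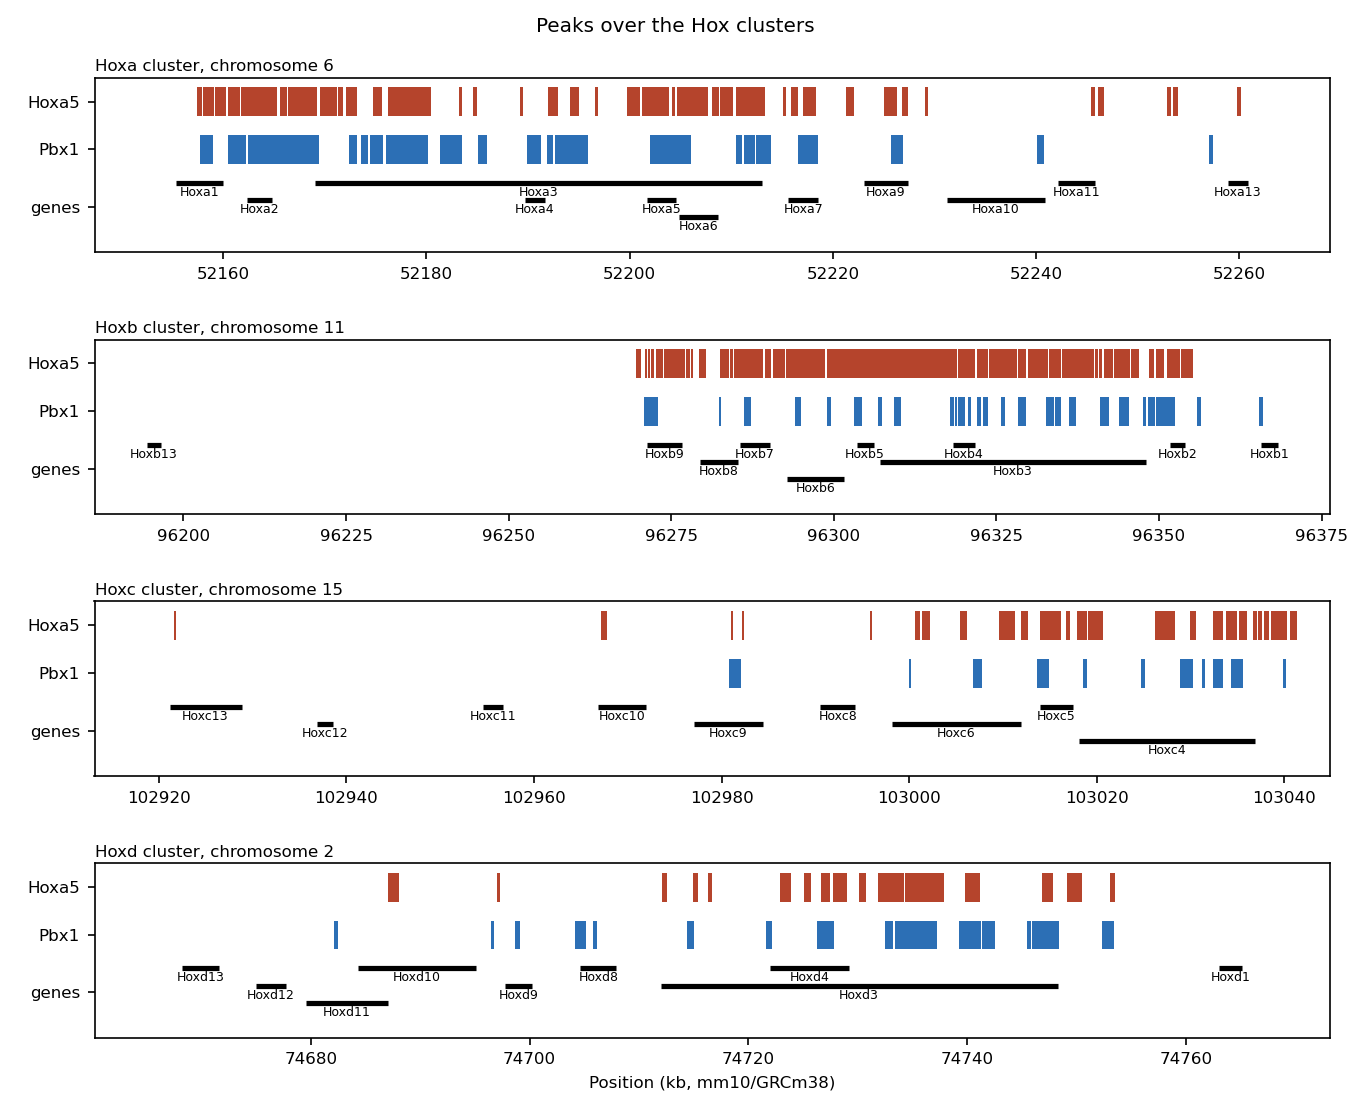
Hoxa5 peaks (red), Pbx1 peaks (blue) and Hox genes (black) along the Hoxa, Hoxb, Hoxc and Hoxd clusters (x axis, position in kb, mm10). Hoxa5 peaks covered 43.2% of the Hoxb cluster, the highest share of the 4 clusters, and Pbx1 peaks covered 34.5% of the Hoxa cluster, their highest share.

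In each peak class the window of 100 kb with the most peaks lay at a Hox cluster. The window holding Hoxc4, Hoxc5 and Hoxc6 (chromosome 15, 103000000 to 103099999) had 24 Hoxa5 peaks, and the window from Hoxb6 to Hoxb1 (chromosome 11, 96300000 to 96399999) had 21 Pbx1 peaks and 14 shared peaks. The highest counts in 200 random placements were 6, 8 and 4. Windows at Hox genes made up 6 of the top 10 for Hoxa5, 4 for Pbx1 and 6 for shared peaks. Other windows dense in Pbx1 peaks were at Ebf3 (13 peaks), Tshz1 (12), Dmbx1 (11), Skap2 (11), Tox3 (11) and Lrmda (10), and windows dense in shared peaks were at Zfp503 (7), Sall1 (6), Meis1 (5) and Bahcc1 (5). Bahcc1 also held 12 Hoxa5 peaks. The remaining dense Hoxa5 windows held 16 peaks at Mir9-2, 14 at Mir9-1 and 13 at Mir9-3, the genes of the neural microRNA miR-9.

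Genes of the TALE class, to which Pbx1 and its partners Meis and Prep (Pknox1) belong, carried peaks of both factors. Hoxa5 peaks were assigned to 12 of 18 TALE genes (random mean 3.72, adjusted permutation p = 0.00180), Pbx1 peaks to 15 (9.09, adjusted p = 0.00491) and shared peaks to 5 (1.27, adjusted p = 0.0244). Meis1 had 11 Hoxa5 peaks (strongest 11.7), 18 Pbx1 peaks (55.1) and 5 shared peaks, and Meis2 had 7 (12.6), 19 (40.0) and 5. Pknox1 had no Hoxa5 peak and 2 Pbx1 peaks with a strongest fold enrichment of 81.2, and Pbx3 had 1 Hoxa5 peak (7.48) and 19 Pbx1 peaks (55.8). The Pbx1 gene (chromosome 1, 168119364 to 168432365) had 13 Pbx1 peaks with a strongest value of 19.4 and no Hoxa5 peak. The shared-peak result of the TALE list missed the threshold in 3 of 8 alternative settings (adjusted p from 0.00637 to 0.173).

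Factors that set motor neuron identity carried a peak more often than random genes. Of 26 such genes, 19 had a Hoxa5 peak (random mean 5.12, adjusted permutation p = 0.000706), 23 a Pbx1 peak (12.4, adjusted p = 0.000706) and 7 a shared peak (1.75, adjusted p = 0.00522). Lhx1, a LIM homeodomain gene of limb-innervating motor neurons and interneurons, had 4 Hoxa5 peaks with a strongest value of 14.9. Ebf3 had 3 Hoxa5 peaks (9.07), 20 Pbx1 peaks (19.9) and 2 shared peaks, and Rbfox3, which encodes the neuronal antigen NeuN, had 4 (9.01), 8 (20.6) and 1. Tshz2 had 1 Hoxa5 peak (8.79) and 16 Pbx1 peaks (48.6). Neurog2, a proneural gene, had 2 Hoxa5 peaks (8.75), 2 Pbx1 peaks (10.2) and 1 shared peak. Esrrg (42.1) and Nkx6-1 (40.8) had Pbx1 peaks and no Hoxa5 peak. Isl1 (chromosome 13, 116298270 to 116309688), a LIM homeodomain gene required for motor neuron generation, had 1 Hoxa5 peak of 6.43 at 455 bp and 1 Pbx1 peak of 6.71 at 54688 bp, which did not overlap.

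Most genes of phrenic motor neurons had a Pbx1 peak. Of 14 genes, 13 had a Pbx1 peak (random mean 7.77, adjusted permutation p = 0.00286), 7 a Hoxa5 peak (3.02, adjusted p = 0.0610, past the threshold only in 3 of 8 alternatives) and 5 a shared peak (1.03, adjusted p = 0.0134). The 5 genes with a shared peak were Hoxa5, Hoxb5, Hoxc5, Tshz1 and Cdh22. Tshz1 (chromosome 18, 84011627 to 84087708) had 4 Hoxa5 peaks (strongest 8.43) and 11 Pbx1 peaks (83.8), of which 3 Hoxa5 peaks were shared, and Cdh22 had 4 (9.81), 12 (14.8) and 2. The POU factor gene Pou3f1 (chromosome 4, 124657646 to 124660655) had 3 Pbx1 peaks, the strongest of 22.4 at 41902 bp, and no Hoxa5 peak. Alcam (chromosome 16, 52248996 to 52453081), an adhesion molecule gene, had 2 Pbx1 peaks (7.17), Ptn (chromosome 6, 36714924 to 36810179) had 4 (17.2 at 69827 bp) and Cdh10 (chromosome 15, 18818869 to 19016206) had 2 (9.13), all without a Hoxa5 peak. Pappa (chromosome 4, 65124174 to 65357509) had no peak of either factor. With the 3 Hox5 genes removed, a step added after the data were seen, 10 of 11 genes had a Pbx1 peak (random mean 7.50, adjusted permutation p = 0.250) and 2 a shared peak (0.970, adjusted p = 0.680), so both results missed the threshold. Both also missed it in the planned setting of peaks over 1 kb from a gene end, where 10 of 14 genes had a Pbx1 peak (7.01, adjusted permutation p = 0.139) and 3 a shared peak (0.678, adjusted p = 0.0967). These were the 2 of 8 alternatives in which they missed it, and over all 8 adjusted p ranged from 0.000444 to 0.250 for Pbx1 and from 0.000857 to 0.680 for shared peaks.

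Cholinergic genes, limb motor column and pool genes, cadherins and delta protocadherins did not pass the test in any peak class under the main setting. Hoxa5, Pbx1 and shared peaks were at 3, 3 and 1 of 9 cholinergic genes (adjusted permutation p = 0.347, 0.830 and 0.778). Chat, the acetylcholine-synthesising enzyme gene, had 1 Hoxa5 peak (7.19) and 1 Pbx1 peak (7.80), and Slc18a3, the vesicular transporter gene within Chat, had 1 Hoxa5 peak (5.54). Chrnb4 had the 1 shared peak (6.91, 34494 bp from the gene), and no cholinergic gene had a shared peak with assignment within 20 kb. In the limb list the counts were 9, 20 and 4 of 24 (adjusted permutation p = 0.238, 0.0532 and 0.343). The strongest Pbx1 peaks of that list were at Nkx6-1 (40.8), Fign (36.6, 74676 bp from the gene) and Foxp1 (35.4). Foxp1, a factor of limb motor columns, had 21 Pbx1 and 2 Hoxa5 peaks, none shared. The limb list was above random lists for Pbx1 in 3 of 8 alternatives, namely without matching on territory (adjusted permutation p = 0.000444), among peaks over 1 kb from a gene end (0.00835) and with assignment to the nearest gene end (0.00750). In the cadherins the counts were 5, 14 and 2 of 19 (adjusted permutation p = 1, 0.740 and 1), led for Pbx1 by Cdh11 (18.0), Cdh12 (16.6) and Cdh9 (16.5). In the delta protocadherins they were 5, 9 and 0 of 10 (adjusted permutation p = 0.230, 0.3005 and 0.898), with strongest peaks at Pcdh8 for Hoxa5 (7.15) and Pcdh7 for Pbx1 (15.6). Without matching on territory, which ignores how much sequence a gene draws peaks from, limb genes for Hoxa5 (adjusted permutation p = 0.0207), cadherins for Pbx1 (0.000444) and delta protocadherins for Hoxa5 (0.0383) and Pbx1 (0.00160) were also above random lists, and in no other alternative.

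More axon guidance genes than genes of random lists carried a peak of each class. Of 57 genes, 32 had a Hoxa5 peak (random mean 12.8, adjusted permutation p = 0.000706), 47 a Pbx1 peak (33.5, adjusted p = 0.000706) and 15 a shared peak (4.51, adjusted p = 0.00126). The strongest Hoxa5 peaks were at the semaphorin gene Sema3f (12.9), the adhesion molecule gene Nrcam (9.42), the GDNF receptor gene Gfra1 (9.20) and the ephrin gene Efnb2 (9.12). The strongest Pbx1 peaks were at Efnb2 (41.8), Nrcam (36.4), L1cam (30.6) and the netrin receptor gene Dcc (30.1). Shared peaks were strongest at Nrcam, Gfra1, Rgma (9.05) and Nrp2 (8.54).

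Genes of neural progenitors and of interneurons were above random lists for both factors. Of 33 progenitor genes, 18 had a Hoxa5 peak (random mean 5.84), 27 a Pbx1 peak (12.9) and 13 a shared peak (1.98), each with an adjusted p of 0.000706. Sox2, a factor of neural stem cells, had 6 Hoxa5 peaks (strongest 14.8) and 7 Pbx1 peaks (18.0). Pbx1 peaks were strongest at Gli2 (58.9, 57165 bp from the gene) and Pax6 (47.2). Shared peaks were strongest at Neurog2 (8.75), the Notch ligand gene Dll1 (7.95) and Gli2 (7.76, 57192 bp from the gene). Of 28 ventral interneuron genes, 20 had a Hoxa5 peak (5.39, adjusted permutation p = 0.000706), 22 a Pbx1 peak (12.3, adjusted p = 0.00126) and 10 a shared peak (1.83, adjusted p = 0.000706). Lhx5 had 8 Hoxa5 peaks (14.8), Pax2 6 (12.95) and Vsx2, a V2a interneuron gene, 4 (10.4), and Uncx had 6 Hoxa5 peaks (10.1) of which 5 were shared. Of 26 dorsal interneuron genes, 21 had a Hoxa5 peak (4.56), 22 a Pbx1 peak (9.75) and 8 a shared peak (1.52), each with an adjusted p of 0.000706. Lbx1 had 5 Hoxa5 peaks (7.78), of which 3 were shared, and Lmx1b had 10 (6.81), of which 3 were shared. With the stronger 50% of each list, shared peaks of the dorsal list missed the threshold (adjusted permutation p = 0.0678, over alternatives 0.000444 to 0.0678).

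**Figure D4:**
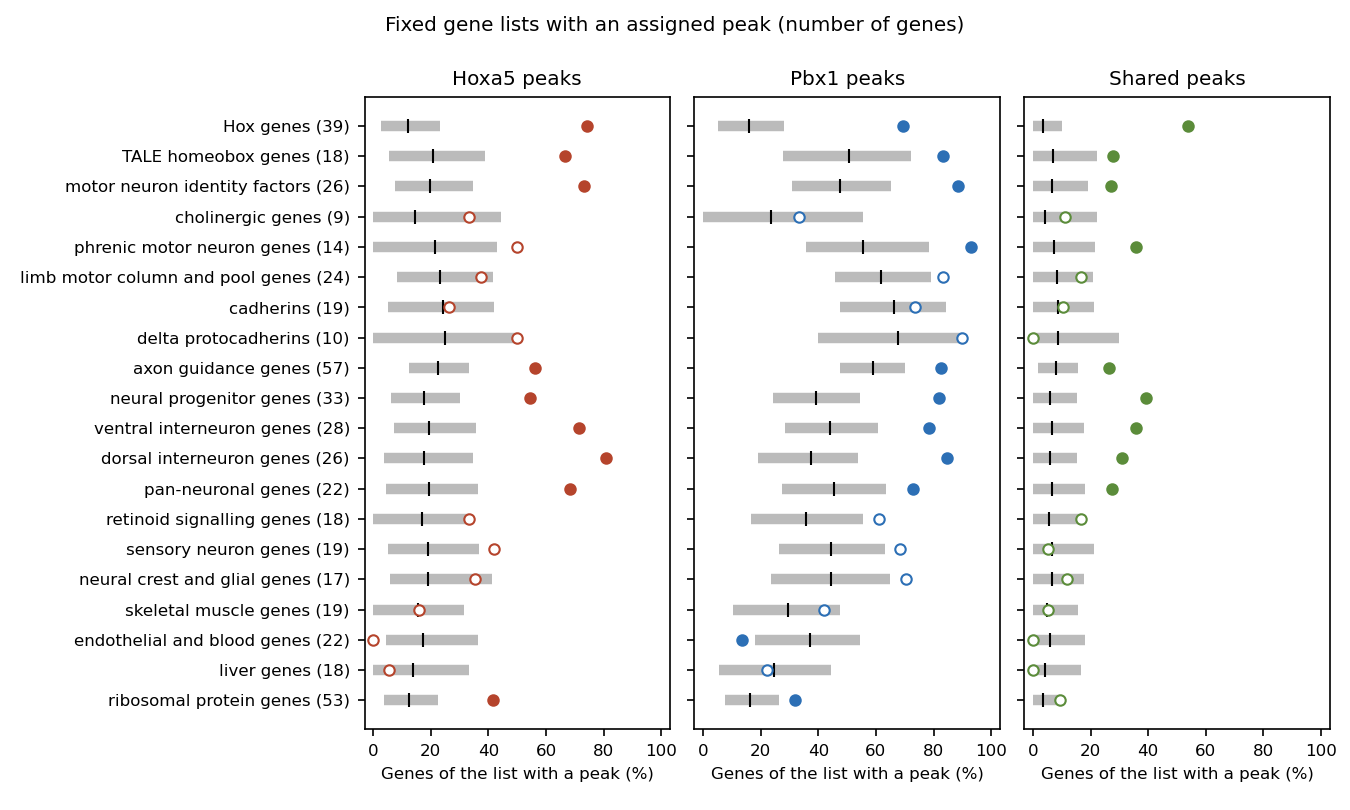
Percent of the genes of each fixed list with an assigned Hoxa5, Pbx1 or shared peak (circles, filled where the adjusted p was under 0.05), with the mean (tick) and the central 95% (grey bar) of 10000 random lists matched on size and territory length. Hox genes stood at 74.4%, 69.2% and 53.8%, and endothelial and blood genes at 0%, 13.6% and 0%.

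Of 22 pan-neuronal genes, 15 had a Hoxa5 peak (random mean 4.26, adjusted permutation p = 0.000706), 16 a Pbx1 peak (10.02, adjusted p = 0.0169) and 6 a shared peak (1.45, adjusted p = 0.0115). Ina, an intermediate filament gene, had 3 Hoxa5 peaks (strongest 10.3) and no Pbx1 peak, and the neurofilament gene Nefl had 3 (8.51) and 5 (31.1). The Pbx1 result missed the threshold in 2 of 8 alternatives (adjusted p from 0.000444 to 0.121) and the shared result in 1 (0.00348 to 0.223). Retinoid signalling, sensory neuron, and neural crest and glial genes did not pass the test under the main setting. Their counts for Hoxa5, Pbx1 and shared peaks were 6, 11 and 3 of 18 retinoid genes (adjusted permutation p = 0.202, 0.0610 and 0.220), 8, 13 and 1 of 19 sensory genes (0.0553, 0.0586 and 1), and 6, 12 and 2 of 17 crest and glial genes (0.238, 0.0553 and 0.740). For Pbx1, crest and glial genes rose above random lists in 4 of 8 alternatives (adjusted permutation p from 0.00124 to 0.198 over all 8), and retinoid (0.0148 to 0.151) and sensory genes (0.000444 to 0.910) in 2 each. For Hoxa5, sensory genes did so in 3 (adjusted permutation p from 0.00600 to 0.807), and retinoid (0.00655 to 0.622) and crest and glial genes (0.0159 to 0.578) in 1 each, as did retinoid genes for shared peaks (0.0368 to 0.636). The retinoic acid receptor genes Rara (64.5) and Rarb (49.1) had the strongest Pbx1 peaks of the retinoid list, and each had 1 shared peak.

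The liver, skeletal muscle, endothelial and blood, and ribosomal protein lists had been fixed as controls. No list of a tissue outside the nervous system rose above random lists, whereas ribosomal protein genes did for each factor. Passing this test in the main setting is therefore not particular to genes of the nervous system. No endothelial or blood gene of 22 had a Hoxa5 peak (random mean 3.83, adjusted permutation p = 0.0534), none had a shared peak (1.29, adjusted p = 0.660), and 3 had a Pbx1 peak (8.13), which was below random lists (adjusted p = 0.0360) but not in 5 of 8 alternatives (0.0110 to 0.226). The 3 were Emcn (15.0), Erg (10.95) and Ptprc (6.52). In skeletal muscle genes the counts for Hoxa5, Pbx1 and shared peaks were 3, 8 and 1 of 19 (adjusted permutation p = 1, 0.371 and 1), and in liver genes 1, 4 and 0 of 18 (0.659, 1 and 1). Of 53 ribosomal protein genes, 22 had a Hoxa5 peak (6.53, adjusted permutation p = 0.000706), 17 a Pbx1 peak (8.67, adjusted p = 0.0138) and 5 a shared peak (1.87, adjusted p = 0.126), with the strongest at Rpl23 for Hoxa5 (12.3) and at Rplp0 for Pbx1 (77.9). Among peaks over 1 kb from a gene end, 3 of the 53 genes had a Hoxa5 peak (random mean 1.80, adjusted permutation p = 0.677, over alternatives 0.000444 to 0.677) and 7 a Pbx1 peak (3.68, adjusted p = 0.192). The Pbx1 result missed the threshold in 5 of 8 alternatives (0.00672 to 0.807).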

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

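The tests in this part were chosen before their results were seen, except the placement at random gene ends for the overlap, the comparison of the strongest 10% of each list near gene ends and the test of list length alone, which were added afterwards.

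Outside chromosomes 1 to 19 and X, which no comparison used, the Pbx1 list held 11 peaks. They drew attention because they lie in sequence left out of the comparisons: 2 are on the mitochondrial genome (−log10 q-values 186 and 80.7) and the others on unplaced or unlocalised sequence, with a strongest fold enrichment of 25.9. The Hoxa5 list held 2 such peaks, of 7.86 and 6.48, and none on the mitochondrial genome.

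The overlap of the lists was 45.8-fold above random placement. Gathering of both factors within 1 kb of protein-coding gene ends does not account for all of it. Peaks over 1 kb from such ends overlapped 55.0-fold above placements, although placements at random protein-coding gene ends lowered the ratio to 9.11. Peaks at the ends of other genes were not left out, so gathering there stays open. Chance meeting of wide peaks is argued against by the summits within 100 bp, which were 92.4-fold above placements. Open sites that give signal with any antibody remain a possible source: 21.8% of the strongest 10% of Pbx1 peaks by fold enrichment carried a Hoxa5 peak, and neither accessibility nor input signal was analysed here to tell this apart from joint binding. No biological explanation was tested, since the design has no condition that separates joint from independent binding.

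Hoxa5 peaks were concentrated at the Hox genes, with 115 peaks assigned to them against 2.02 in placements. The density of protein-coding gene ends does not account for this. Placements that kept each peak's distance from such an end gave 9.31 on average, so that the observed number was 12.4-fold higher. Splitting of a run of signal at gaps under 1 kb does not account for it either. Merged within 1 kb, the peaks formed 47 runs, against at most 9 in placements. Signal over a whole cluster, cut at wider gaps, stays open. Such gaps were not merged, and the placements set each peak independently. Signal that any antibody gives at these clusters may contribute, since Pbx1 peaks were raised there too, although by less: 15.3-fold against 56.9-fold for Hoxa5 over uniform placements, and 3.69-fold against 12.4-fold over placements that kept the distance from a gene end. The depth and the floors differ between the lists, so the unequal ratios do not settle it, and it cannot be told apart from binding by both factors.

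Hoxa5 peaks lay near gene ends in 53.1% of cases and Pbx1 peaks in 19.4%. The greater length of the Pbx1 list alone is argued against, since its 4497 strongest peaks by −log10 q-value had 25.4% near a gene end (24.1 to 26.7), below the interval of the Hoxa5 list. In the top quartile of fold enrichment the shares were still apart, at 52.1% for Hoxa5 and 26.05% for Pbx1. They lay close together in a smaller cut. In the strongest 10% of each list by fold enrichment the shares were 41.4% for Hoxa5 (37.0 to 46.0) and 36.6% for Pbx1 (34.2 to 39.1; Fisher's exact test, p = 0.0670), and by −log10 q-value they were 38.5% (34.1 to 43.1) and 39.8% (37.3 to 42.3; p = 0.660). A Pbx1 list cut to the Hoxa5 length tests length but not the different floors of the lists, so a difference in filtering stays open as a source of the contrast. Weak Hoxa5 peaks passed by the authors' filter stay open too. The stronger 50% of the Hoxa5 list by −log10 q-value had 52.4%, within the interval of the full list. By quartile of fold enrichment the Hoxa5 share was 51.1%, 55.8%, 53.4% and 52.1% from weakest to strongest, with no steady fall. The strongest 10% of the Hoxa5 list, however, fell below the interval of the full list. The antibodies, library depths and filters differ between the lists together with the factor, so a difference between the proteins was not tested.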

How the results depend on the processing

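Among the alternatives reported here, placement at random gene ends, leaving out peaks assigned to Hox genes, assignment to the nearest gene end, the shorter Pbx1 list for the gene lists, gene lists without Hox genes, widths compared by summits within 100 bp and the strongest 10% of each list were chosen after the data were seen. The stronger 50% and the shorter Pbx1 list were ranked by −log10 q-value. The share of Hoxa5 peaks with a Pbx1 partner, 30.1%, was 25.5% with 50% of the Hoxa5 peak covered, 12.3% with reciprocal overlap of 50%, 11.5% with summits within 100 bp, 27.4% in the stronger 50% of each list and 16.7% against a Pbx1 list as long as the Hoxa5 list; these definitions admit fewer pairs by construction. The ratio to placements stayed past the threshold in all 9 alternatives, from 9.11 to 92.4. Shares near a gene end, 53.1% for Hoxa5 and 19.4% for Pbx1, were 37.4% and 15.6% within 500 bp, 74.7% and 29.2% within 5 kb, and 60.2% and 24.3% with the ends of all annotated genes. In the stronger 50% of the Pbx1 list the share was 21.9%, and the upper 2 quartiles by fold enrichment had 15.4% and 26.0%. In the strongest 10% the Hoxa5 and Pbx1 shares were 41.4% and 36.6% by fold enrichment and 38.5% and 39.8% by −log10 q-value, so the contrast of the lists depended on the cut; the cause was not tested. Shared peaks had the higher median in all 6 alternatives for Pbx1 and in 5 of 6 for Hoxa5. The exception was width by summits within 100 bp, with shared minus unshared Hoxa5 peaks at −14 bp (permutation p = 0.252); overlap by 1 bp favours wide peaks. The densest windows changed by less than 1.5 times.

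Gene lists above random lists numbered 9 for Hoxa5 (9 to 13 over alternatives), 10 for Pbx1 (8 to 15) and 9 for shared peaks (6 to 9). The 1 list below random, endothelial and blood genes for Pbx1, became 0 with assignment within 20 kb, without matching, with the stronger 50%, with peaks over 1 kb from a gene end and with the shorter Pbx1 list; the cause was not tested. Of 480 list results under alternatives, 434 kept their side of the threshold, 22 fell short of it, 24 newly passed it and 0 reversed. Of 29 called list results, 20 were called in all 8 alternatives, and 13 results not called in the main setting were called in at least 1. No paired analysis was possible because the groups share only replicate number 1 and each antibody has 1 library. The 5 motif alternatives were not run. Unknown depth and the authors' floors on the lists limit every absence of a peak, so a gene counted without a peak had none above these floors.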

Other observations

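The tests of microRNA genes against placements and of motor neuron against interneuron genes in this part were chosen after the pattern was seen.

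Hoxa5 peaks were wide and strong at 5 of the 6 genes of miR-9 and miR-124, microRNAs abundant in neurons and their progenitors. A Hoxa5 peak overlapped Mir9-1 (chromosome 3, 88215598 to 88215686), Mir9-2 (chromosome 13, 83738814 to 83738885), Mir9-3 (chromosome 7, 79505264 to 79505353), Mir124a-1 (chromosome 14, 64590657 to 64590741) and Mir124a-2 (chromosome 3, 17795662 to 17795770). The strongest Hoxa5 peaks within 10 kb of these genes had fold enrichments of 21.8, 20.1, 14.7, 13.6 and 14.3, and the widest were 4324, 4614, 3641, 4180 and 5657 bp. Mir124a-3 (chromosome 2, 180894040 to 180894107) had 5 Hoxa5 peaks within 10 kb, the strongest of 9.01 and the widest of 1163 bp, and none overlapped it. Pbx1 peaks within 10 kb numbered 3 at Mir9-1, 8 at Mir9-2, 3 at Mir9-3, 4 at Mir124a-1, 6 at Mir124a-2 and 0 at Mir124a-3, with the strongest, 46.9, at Mir9-3. The 6 genes were picked because their Hoxa5 peaks had been seen, so no test can set them against the rest. Of the 1222 other microRNA genes, 160 lay within 10 kb of a Hoxa5 peak (13.1%, 11.3 to 15.1), against 3.67% in uniform placements of the peaks and 9.29% in placements that kept the distance from a gene end, and the observed number was above all 1000 placements of each kind (at most 102 and 152). Hoxa5 peaks thus lay near the other microRNA genes more often than in either kind of placement. Whether this tendency accounts for the peaks at the 6 picked genes stays open. For Pbx1, 239 of the others lay within 10 kb (19.6%), against 11.2% and 21.6% in the placements.

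A hypothesis was that Hoxa5 lies more often at motor neuron genes than at genes of other spinal neurons. It was not borne out: 19 of 26 motor neuron identity factors (73.1%) and 39 of 52 interneuron genes (75.0%) had a Hoxa5 peak, an odds ratio of 0.905 (Fisher's exact test, p = 1). The interneuron genes were the 28 ventral and 26 dorsal genes of the report, with Foxd3, which is in both lists, counted once and Lhx1, which is also a motor neuron factor, left out; both had a Hoxa5 peak. The gene lists are not exclusive to 1 cell type, so the comparison holds for these lists only. The lists were not matched on territory length, and with so few genes a difference between them is not excluded. Neurog2 and Nkx6-1 are also in the progenitor list, and Pax3 of the dorsal list is also in the muscle list. The tissue was whole cervical cord, so peaks in motor neurons and in other cells cannot be separated in these lists.

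Both lists were sparse on the X chromosome. It held 39 Hoxa5 peaks, or 0.229 per Mb against 1.83 on the autosomes, where the range was 1.03 (chromosome 16) to 3.58 (chromosome 11). It held 174 Pbx1 peaks, or 1.02 per Mb against 6.02, with an autosomal range of 4.70 (chromosome 16) to 8.19 (chromosome 11). Per protein-coding gene, the X chromosome had 0.187 times the autosomal density of Hoxa5 peaks and 0.253 times that of Pbx1 peaks. Neither mappability nor the authors' filter was tested as a source of this deficit, so its cause is open.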
